A study of Mus musculus with 2 samples.

How the data were processed

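Total RNA from sorted small intestinal epithelial cells of mice was amplified, coupled to Cy3 or Cy5 and hybridised to Toray two-colour arrays, per the labels' protocols. There were 3 sorted populations and 2 arrays, 1 for each comparison with the EGFP-only population. That population carried Cy5 on both arrays, per the labels, so no dye swap was made. Cells were pooled from 4 mice before sorting and each fraction is 1 biological replicate. Whether both arrays received the same EGFP-only extract or labelling reaction is not given in the sources used here.

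The authors deposited 1 scanner file per array, with the median intensity of each spot in red and green, per the file headers. No background had been subtracted, judging from the values, since blank spots lie well above 0. The headers list 3 scanner gains and lines fitted between them. The columns headed as background medians followed the brightness of the spot itself, with correlations of log2 values from 0.937 to 0.958, so they were not used as local background. The authors also deposited normalized log2 ratios, Cy3 population over EGFP only, per the labels' descriptions. How these were made was inferred from the values. Subtracting from each channel the mean of the blank spots without the highest and lowest 5%, taking the log2 ratio and centring it gave the deposited value within 0.02 for 99.99% of probes with a value on each array. A deposited value was missing where a channel lay within 2 SD of the trimmed blank mean (same status for 99.98% and 100% of probes). Each of these columns had a median of 0, and their scale, centring and direction are thereby known.

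Each array had 27456 spots, of which 3982 were controls, 2736 of them blank. Spot intensities were corrected with normexp and an offset of 50, without local background, and normalized within each array by loess, with controls and quality-marked spots at weight 0 (limma 3.58.1 in R 4.3.3). Quality-marked probes, 2 on the first array and 3 on the second, were left out. A probe counted as above background when its intensity exceeded the mean plus 2 SD of the blanks. By this limit 68.9% of 23474 probes were above background in the EGFP-only and 77.1% in the double-positive channel of the first array, and 67.0% and 72.8% in the EGFP-only and tdTomato-only channels of the second. Median intensities were 98.3, 104, 98.2 and 108 in the same order. The number of arrays limits the precision. Spots at the scanner's ceiling of 65535 were kept and are named as saturated; 25 probes on each array were saturated in Cy3 and none in Cy5. Their ratios are underestimates, and a probe saturated in both Cy3 channels has no ratio in the third comparison. A gene above background in 1 population alone was given a bound. For it the bright level was set against the higher of the dim probe's own level and the lowest level of any probe above background, after loess and Aquantile, which stays open to dye bias.

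Gene names came from the platform's annotation, which named 16632 probes with 1 gene each, none with several, and left 6842 without a name here. Symbols were updated through the synonyms of the mouse RefSeq assembly GRCm38.p6. Of the named probes in the annotation, 12622 symbols were current, 3947 were updated, 59 were ambiguous and 3 unmatched, and these last were kept as given. The build behind the array design is not given in the sources used here, so no coordinates are printed. Probes of a gene above background were averaged, 16390 genes in all. Among 125 genes with several probes in the first comparison, the median range between probes was 0.24 on the log2 scale and 13 had probes on both sides of 2-fold.

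With 1 array for each of the first 2 comparisons, and their difference for the third, no test was made. Genes were counted as higher or lower at a log2 ratio of at least 1 or at most −1. The third comparison is the log2 ratio of the tdTomato-only array minus that of the double-positive array, over probes above background in all 4 channels. The 23 gene lists were fixed before the data were examined. Each list median was set against 10000 random lists of the same size, matched on mean intensity in 10 bins. For the overlap of both comparisons, unchanged populations were simulated 100 times with the spread between the 2 measurements of the EGFP-only channel. The rule for the genes named was fixed beforehand. It asked for Lgr5 and Atoh1, though probes for Atoh1 were not analysed here. It also took the 6 highest and 6 lowest per comparison, up to 3 members of each list with the largest log2 ratio of either sign, and up to 2 members above background in 1 population alone. A gene named in 1 comparison may be given in the others.

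The steps were tested on simulated arrays with the real EGFP-only levels, a dye curve, and 200 genes changed by known folds in either direction. In the double-positive comparison, run on 11698 genes, 8.33% of genes changed 2-fold were counted, 74.5% of those changed 4-fold and 95.5% of those changed 8-fold, with median folds found of 1.62, 2.52 and 4.78. In the tdTomato-only comparison, run on 11199 genes, the shares were 6.82%, 68.9% and 93.0%. In the third comparison, run on 11059 genes, they were 18.2%, 66.7% and 90.9%. The folds found therefore understate the simulated changes, through the offset. None of the unchanged genes was counted in any comparison, but the small simulated spread fixed this in advance. The simulation held technical spread and a smooth dye curve, without spread between sorts or dye effects of single probes. Its changed genes also went evenly in both directions, unlike those on the real arrays. On the real arrays the slope of these log2 ratios on the authors' deposited ones was 0.596 and 0.624.

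Alternatives chosen beforehand were median centring without loess, quantile normalization of all channels, no background correction, no filter or a stricter one on dim probes (above 2 times the limit), the brightest probe of a gene, the authors' deposited ratios, folds of 1.5 and 4, and for the third comparison the Cy3 channels set directly against each other. Subtraction of the blank mean with loess was added after the data were seen. Gene-level steps used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. Over all probes the median of the signed difference between loess and median centring was 0.096 and 0.072 on the log2 scale. Single genes moved more: the median size of the change was 0.379 over the 225 named values.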

Results

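Gene expression was compared among 3 populations of mouse small intestinal epithelial cells on 2 two-colour arrays. The mice carried EGFP at the Lgr5 locus, which marks the crypt base columnar stem cells, and a Cre recombinase driven by Atoh1, the transcription factor that commits cells to the secretory lineage. RU486 given on 5 consecutive days switched on tdTomato permanently in cells with Atoh1-Cre and in all their progeny. At 20 days after recombination, cells pooled from 4 mice were sorted by the 2 fluorescent proteins. Cells with EGFP alone (EGFP only) stood for Lgr5 cells without a recorded Atoh1 history. Cells with both proteins (double positive) stood for Lgr5 cells descended from Atoh1-expressing cells, and cells with tdTomato alone (tdTomato only) for the other descendants. The EGFP-only RNA carried Cy5 on both arrays, and 1 of the other populations carried Cy3 on each.

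The first 2 comparisons rest on 1 array each and the third on the difference between these arrays, so no ratio below has a replicate error or a p-value, and genes were counted by size, at least 2-fold. The EGFP-only channel was measured on both arrays. Its 2 measurements differed with an SD of 0.083 on the log2 scale over 15640 probes, and 4 of these probes were at least 2-fold apart, which describes technical spread only. Of 23474 probes, 16176 were above background in the EGFP-only channel and 18091 in the double-positive channel of the first array. On the second array 15722 and 17078 were above background in the EGFP-only and tdTomato-only channels. Probes for Atoh1 were not analysed here.

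The first comparison asked how Lgr5 cells with an Atoh1 history differed from Lgr5 cells without one. Lgr5 itself was 1.20-fold higher in the double-positive population (log2 ratio 0.26), a value that median centring without loess turned to −0.26. All 13 measured Paneth cell genes, of 45 listed, were at least 2-fold higher, with a median of 17.2-fold. That log2 median of 4.11 was 3.45 in the authors' deposited ratios, 3.02 with median centring and 2.88 after quantile normalization, and 7 of the 13 had saturated Cy3 spots. Clps, which encodes colipase, was 46.9-fold higher, the lipase gene Pnliprp2 43.8-fold and the stress-response gene Nupr1 29.8-fold. All 41 measured cell cycle genes lay below the EGFP-only level, with a median log2 ratio of −0.65, and −1.19 with median centring.

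Goblet cell genes and genes of the secretory machinery were higher as well. Of 26 measured goblet cell genes, 20 were at least 2-fold higher and none was 2-fold lower. Their median was 3.50-fold, above every one of 10000 random lists of the same size and brightness, and on the log2 scale 1.81, with 1.11 under median centring and 2.25 with the blank mean subtracted. Ccl6 was 22.2-fold higher, the guanylin gene Guca2a 12.2-fold, and Spink4 11.5-fold with its Cy3 spot saturated. Genes of the unfolded protein response and secretion had a median of 2.19-fold (log2 1.13, but 0.94 in the deposited ratios and 0.49 with median centring), and 14 of 27 were at least 2-fold higher. Ern2, the endoplasmic reticulum stress sensor of mucus-secreting cells, was 8.91-fold higher, and the chaperones Dnajb9 and Dnajc3 6.65-fold and 5.39-fold. The 10 genes of secretory progenitors had a median log2 ratio of 0.25, which median centring turned to −0.09. Spdef (2.53), Cbfa2t3 (2.23) and Gfi1 (1.79) were past 2-fold. Neurog3, which specifies enteroendocrine cells, had −1.55.

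Enteroendocrine genes went the other way, with a median log2 ratio of −0.25 over 30 genes, and −0.74 in the deposited ratios and −1.02 with the blank mean subtracted. Those at least 2-fold lower were Neurog3, the ghrelin gene Ghrl (−1.49), Gip (−1.43), Cck (−1.18) and, named after their values were seen, Chgb (−1.30) and Chga (−1.04). Of the 6 members above 0, Reg4 at 4.46 was the only one past 2-fold. Tuft cell genes had a median of −0.09 over 19 genes (−0.44 with the blank mean subtracted), and Cd24a (1.68), which Paneth cells also express, was the only member past 2-fold. Enterocyte genes had a median of 1.82-fold (log2 0.86, but 1.5 in the deposited ratios and 1.58 with the blank mean subtracted), and 16 of 33 were at least 2-fold higher, including the apolipoprotein gene Apoc2 (12.7-fold), the lectin gene Reg3g (8.97-fold) and the ileal bile acid binding protein gene Fabp6 (7.94-fold).

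Stem cell genes were mixed. Of 33 genes, 24 lay below 0 and the median log2 ratio was −0.28 (−0.75 with median centring), which only 0.01% of random lists undercut. The secreted glycoprotein gene Olfm4 was 2.94-fold lower, and Aqp4 (−1.19) and Cdca7 (−1.18) were also past 2-fold. The RNA-binding protein gene Msi1 (2.23), the ephrin receptor gene Ephb3 (1.52), which Paneth cells also express, and Jun (1.13) were at least 2-fold higher. Aqp4 and Jun were named after their values were seen. In the cell cycle list, the kinase gene Plk1 (−1.26), the cyclin gene Ccna2 (−1.13) and the replication helicase gene Mcm2 (−1.04) were past 2-fold. Of 6 measured cell cycle inhibitor genes 3 lay above 0, with Cdkn1a at 1.40 and the antiproliferative gene Btg2 at 2.22, and 3 lay below. Btg2 and Jun are also in the list of the dissociation and immediate early response.

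Genes of T cells and intraepithelial lymphocytes, which are not epithelial, were also higher in the double-positive population. Of 17 measured, 14 were at least 2-fold higher, and the median was 3.32-fold (log2 1.73, and 3.21 in the deposited ratios). The granzyme genes Gzma and Gzmb were 14.1-fold and 10.8-fold higher, and the chemokine gene Ccl5 10.6-fold. Of 13 myeloid or mast cell genes, C1qb (3.62), Fcer1g (1.88) and Tyrobp (1.20) were past 2-fold. The list median was 0.08, but 0.89 in the deposited ratios and 0.49 with the blank mean subtracted, and 4 more members were above background in the double-positive channel alone and none in the EGFP-only channel alone. B or plasma cell genes had a median of 0.03 over 5 genes, with Cd79b at 0.38, and median centring or quantile normalization put that median below 0. Fibroblast, muscle and endothelial genes had a median of 0.12 over 6 genes (0.52 in the deposited ratios), and on that array 6 more, such as Sparc (at least 1.33-fold higher), were above background in the double-positive channel alone and 1 in the EGFP-only channel alone. Over all genes 1383 were above background in the former channel alone and 121 in the latter alone, so these splits have the direction of the whole array. Genes of the dissociation and immediate early response had a median of 1.74-fold over 15 genes, but 8 lay above 0 and 7 below. Btg2 (2.22), Egr1 (1.49) and Nr4a1 (1.27) were highest, while members such as Ier2 (−0.31) and Junb (−0.38) lay below 0. Median centring without loess put the list median at −0.14.

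Across all genes, 601 of 11774 were at least 2-fold higher in the double-positive population and 40 were at least 2-fold lower, so that 93.8% of these genes were higher. The split differed between settings: 77.7% were higher in the authors' deposited ratios (1516 higher, 435 lower), 74.5% with the blank mean subtracted and loess kept (1173 and 402), 82.8% after quantile normalization (516 and 107), and 33.0% with median centring alone (364 and 740). The highest ratios belonged to 2410004B18Rik (5.61), Fry (5.60), Clps, the angiogenin genes Ang2 (5.55) and Ang5 (5.50), whose near-identical sequences leave the member uncertain, and Pnliprp2. The lowest were those of Dmbt1 (−2.08), which encodes a mucosal glycoprotein, Olfm4, Neurog3, the cyclophilin gene Ppia (−1.50), Ghrl and the glucuronosyltransferase gene Ugt1a6a (−1.44). A further 1383 genes were above background in the double-positive population alone and 121 in the EGFP-only population alone. Only 12 of the 1383 and 0 of the 121 had a bound of at least 2-fold, so most of them lay near the limit. The offset used in background correction shrinks folds, most in dim genes. No dye swap was made, so a dye effect of single probes cannot be separated from a difference between populations.

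**Figure D1:**
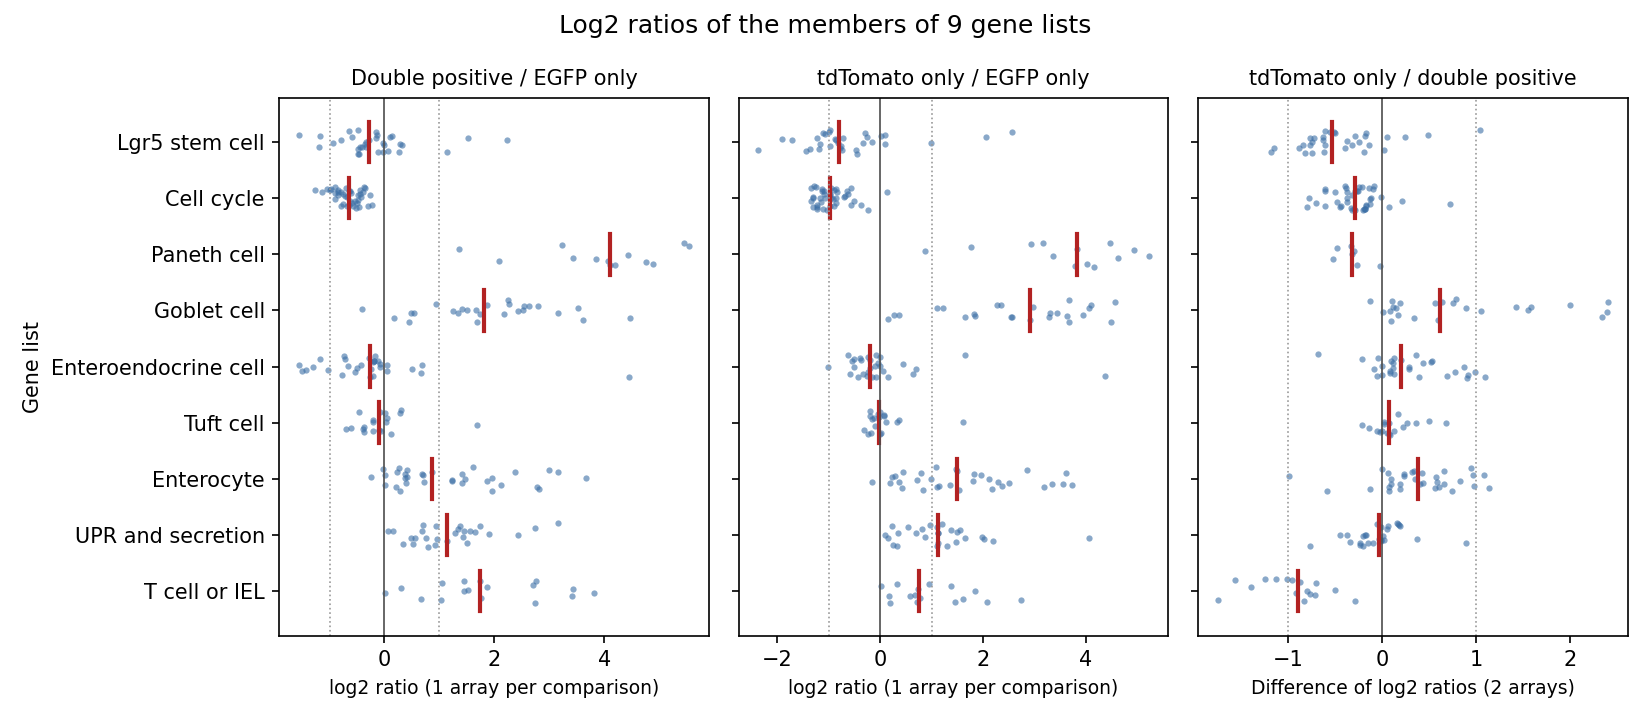
Each point is the log2 ratio of 1 gene of a list fixed before the data were examined, the red bars are list medians, the dotted lines mark 2-fold, and the horizontal scale differs between panels (UPR, unfolded protein response; IEL, intraepithelial lymphocyte). Paneth cell medians lie at 4.11 and 3.82 against the EGFP-only population, cell cycle medians at −0.65 and −0.98, and the lymphocyte median is 1.73 in the double-positive and 0.75 in the tdTomato-only population.

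The second comparison set the descendants of Atoh1-expressing cells without Lgr5-EGFP against the EGFP-only population. Lgr5 was 1.85-fold lower (log2 ratio −0.89). Goblet cell genes had a median of 7.50-fold (log2 2.91, with 2.24 under median centring and 3.61 with the blank mean subtracted), and 22 of 25 measured genes were at least 2-fold higher. Zg16, a granule protein gene of goblet cells, was 23.8-fold higher with its Cy3 spot saturated, Ccl6 22.3-fold and Rep15 17.2-fold. Retnlb, another goblet cell gene, was above background in the tdTomato-only channel alone on that array, at least 3.54-fold higher. In the double-positive population it had a log2 ratio of 2.80, and a bound does not rank the 2 populations. Paneth cell genes had a median of 14.1-fold (log2 3.82, and 2.90 after quantile normalization), with 12 of 13 at least 2-fold higher. Among those without saturated spots, Clps (37.3-fold), Pnliprp2 (30.5-fold) and Nupr1 (24.7-fold) were highest. Others were saturated in Cy3, so their folds are underestimates.

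Stem cell and cell cycle genes were lower. The stem cell list had a median log2 ratio of −0.80 over 32 genes (−1.29 with median centring), 11 of them at least 2-fold lower. Axin2 was above background in the EGFP-only population alone, but with a bound of only 1.12-fold. Olfm4 was 5.17-fold lower, the cell division gene Cdca7 3.75-fold and the gastrokine gene Gkn3 3.28-fold. Ephb3 (2.56) and Msi1 (2.06) were higher here too. The cell cycle median was −0.98 over 41 genes (−1.44 in the deposited ratios and −1.58 with median centring), with 19 at least 2-fold lower, such as Plk1 (−1.35), Mcm6 (−1.35) and Mcm5 (−1.32). Cdkn1a and Btg2 each stood at 2.19, but 3 of the 6 measured cell cycle inhibitor genes lay below 0. Enterocyte genes had a median of 2.80-fold (log2 1.49, and 2.12 with the blank mean subtracted), and 21 of 32 were at least 2-fold higher, with Apoc2 at 13.3-fold, the apolipoprotein gene Apoa1 at 12.2-fold and the fatty acid binding protein gene Fabp1 at 11.8-fold.

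The secretory progenitor list had a median of 0.60 over 10 genes, with 0.31 under median centring and 0.93 with the blank mean subtracted. Spdef (3.29), Cbfa2t3 (2.12), Gfi1 (1.94) and Tmsb10 (1.34) were past 2-fold above, and Stmn1 (−1.54) and Neurog3 (−1.02) below. Unfolded protein response and secretion genes had a median of 2.17-fold (log2 1.12, but 0.74 in the deposited ratios and 0.44 with median centring), with 16 of 27 at least 2-fold higher, including Ern2 (16.6-fold), Dnajc3 (4.59-fold) and the stress transcription factor gene Ddit3 (4.07-fold). Enteroendocrine genes had a median of −0.20 over 29 genes (−0.51 in the deposited ratios) but a mean of 0.04, since Reg4 (4.38) and the secretin gene Sct (1.65) were far above it. The tuft cell median was −0.02, with Cd24a at 1.62.

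Of 16 measured lymphocyte genes, 6 were at least 2-fold higher, and the median was 1.69-fold (log2 0.75, but 1.90 in the deposited ratios and 1.94 with the blank mean subtracted), with Gzmb at 2.73, Gzma at 2.07 and Ccl5 at 1.85. Myeloid or mast cell genes had a median of 0.39 over 9 genes, with C1qb (3.30) past 2-fold, but 1.26 in the deposited ratios and 1.09 with the blank mean subtracted. A further 8 were above background in the tdTomato-only channel alone and 1 in the EGFP-only channel alone. The B or plasma cell median was −0.06 over 4 genes, with no stable sign across settings, and the median of fibroblast, muscle and endothelial genes was 0.15 over 5 (0.81 in the deposited ratios), with 6 more above background in the tdTomato-only channel alone and none in the EGFP-only channel alone. Over all genes these numbers were 1041 and 201, so the splits have the direction of the whole array. The dissociation and immediate early list had a median of 1.98-fold (log2 0.98, but 0.49 in the deposited ratios and 0.19 with median centring), and 7 of 15 were at least 2-fold higher, with Klf6 at 1.46 and Atf3 at 1.45.

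In all, 700 of 11381 genes were at least 2-fold higher and 135 at least 2-fold lower in the tdTomato-only population, 83.8% of them higher. In the authors' deposited ratios the numbers were 1595 and 864 (64.9% higher), with the blank mean subtracted 1225 and 593 (67.4%), after quantile normalization 580 and 252 (69.7%), and with median centring alone 407 and 850 (32.4%). The highest ratios were those of Clps, Ido1 (4.99), which encodes a tryptophan-degrading enzyme, Pnliprp2, the calcium-binding protein gene S100a6 (4.92), Npff (4.84) and Sprr2b (4.76). The lowest were those of Olfm4, Cdca7, Ppia (−1.78), the elongation factor gene Eef1a1 (−1.73), Gkn3 and the ribosomal protein gene Rps3 (−1.62). A further 1041 genes were above background in the tdTomato-only population alone and 201 in the EGFP-only population alone, of which 14 and 0 had a bound of at least 2-fold.

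The third comparison set the tdTomato-only population against the double-positive one, through the difference of the 2 arrays' log2 ratios, in which the EGFP-only reference and any dye effect shared by both arrays cancel. Lgr5 was 2.21-fold lower in the tdTomato-only population. Goblet cell genes were higher, with a median of 1.53-fold and 8 of 24 at least 2-fold, among them Zg16 (5.28-fold, saturated in the tdTomato-only channel), Tpsg1 (5.24-fold) and Bcas1 (5.06-fold). Lymphocyte genes were lower, all 16 of them below 0 with a median of −0.89 (−1.28 in the deposited ratios), led by Gzma (−1.75), Ccl5 (−1.56) and Cd7 (−1.39).

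The 7 Paneth cell genes with a ratio had a median of −0.32 and all lay below 0 and within 2-fold, with Pnliprp2 at −0.52 and Wnt3 at −0.48. The other 6 were saturated in both Cy3 channels and have no ratio here. Stem cell genes had a median of −0.53 over 32 genes. The ion transporter gene Slc12a2 (−1.18) and Lgr5 (−1.14) were past 2-fold below and Ephb3 (1.04) above. The cell cycle median was −0.29, with none of 41 genes past 2-fold and with Mcm4 at −0.79. The enterocyte median was 0.38, with Reg1 (1.14) and Lypd8 (1.08) past 2-fold and Reg3g at −0.99. The enteroendocrine median was 0.20 (0.59 in the deposited ratios), with Cck at 1.09, and the tuft cell median 0.07, with Avil at 0.68. In the secretory progenitor list, with a median of 0.13, Tmsb10 stood at 1.10. The unfolded protein response and secretion median was −0.04 and turned to 0.03 with median centring. Myeloid or mast cell genes had a median of −0.11, with Fcer1g at −1.12 and a median above 0 in the authors' deposited ratios, B or plasma cell genes one of −0.09, and fibroblast, muscle and endothelial genes one of −0.04. The dissociation and immediate early median was 0.27, with Ier2 at 0.70.

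Of 11311 genes, 92 were at least 2-fold higher in the tdTomato-only than in the double-positive population and 31 were at least 2-fold lower, 74.8% of them higher. In the authors' deposited ratios 216 were higher and 215 lower, 50.1% higher, and with the blank mean subtracted 206 and 163, 55.8% higher. The chromatin remodelling gene Smarcd3 (13.1-fold) and S100a6 (13.0-fold) were highest, followed by the glutathione transferase gene Gsta4 (2.56), the actin-severing protein gene Scin (2.48), Zg16 and Abi3bp (2.40). The lowest were the acyl-CoA synthetase gene Acsl6 (−3.61), Lim2 (−2.49), Pax9 (−2.36), the metallothionein gene Mt2 (−2.31), Dnajc18 (−2.20) and Fry (−2.13).

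Genes at least 2-fold from the EGFP-only population were compared between both tdTomato populations. Among 11318 genes measured in both comparisons, 472 were at least 2-fold higher in both, out of 594 in the double-positive and 699 in the tdTomato-only population, where independent lists would share 36.7. Of 40 and 135 genes at least 2-fold lower, 21 were shared, against 0.477 for independent lists, and no gene was past 2-fold in opposite directions. With median centring 284 were higher and 551 lower in both, in the deposited ratios 1110 and 289, and after quantile normalization 403 and 72. Unchanged populations were simulated 100 times against the shared reference with technical spread alone, without spread between sorts or a dye effect shared by both arrays, so that 0 shared genes was fixed by that small spread. The correlation of the log2 ratios across genes, which are not independent replicates, was 0.88, and the covariance was 0.316. The simulations gave 0.50 and 0.0036. Their reference and both populations had the same spread, which fixes the 0.50, and the small spread fixes the 0.0036. Neither value therefore tests the overlap. Part of the overlap and of the correlation may come from the shared EGFP-only RNA, which could not be split, or from probe dye effects.

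**Figure D2:**
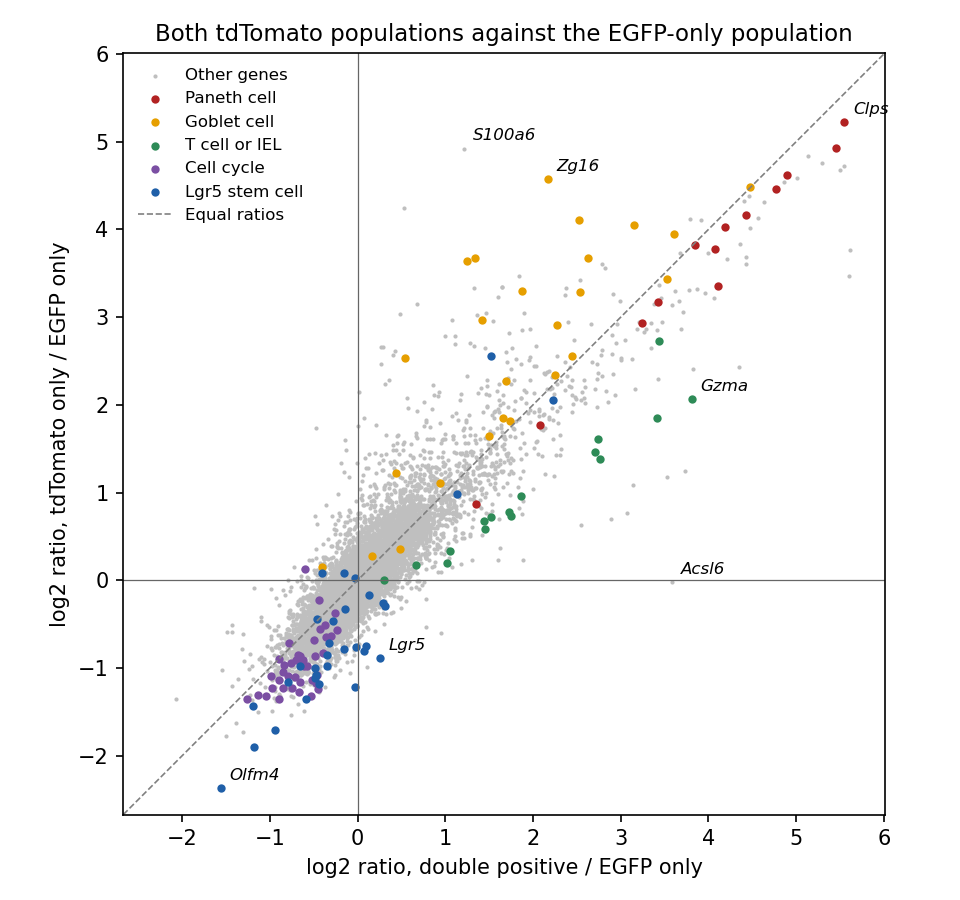
Each point is 1 gene, with its log2 ratio to the EGFP-only population in the double-positive (horizontal) and tdTomato-only (vertical) population, and the dashed line marks equal ratios. Most goblet cell genes, such as Zg16 (2.18 and 4.57), lie above the line, lymphocyte genes, such as Gzma (3.82 and 2.07), below it, and Lgr5 lies at 0.26 and −0.89.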

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

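Of the tests below, those on the Paneth cell and lymphocyte patterns were chosen after the result was seen. For the third pattern the spot test and the share of lymphocyte genes were set beforehand, and the comparison of excesses afterwards, as were the interval and the deposited ratios used for white cells of all kinds.

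Lgr5, Dtx4, Ier2, Junb and Lgals4 stood on opposite sides of the EGFP-only level in the 2 tdTomato populations, each by more than 2 SD (0.166) of the difference between the 2 measurements of the EGFP-only channel. This difference was not tested, since each population was measured once. Lgr5 was at 0.26 in the double-positive and −0.89 in the tdTomato-only population, but at −0.26 and −1.33 with median centring. Dtx4, a gene of the Notch pathway, was at 0.20 and −0.58. The immediate early genes Ier2 (−0.31 and 0.39) and Junb (−0.38 and 0.24), and the galectin gene Lgals4 (−0.46 and 0.65), went the other way. With median centring none of these 5 genes kept opposite sides past that limit: Dtx4 was at −0.32 and −1.05, Ier2 at −0.999 and −0.27, Junb at −0.93 and −0.29, and Lgals4 at −0.94 and 0.14. In the deposited ratios and after quantile normalization only Lgals4 kept them past it. Probes without a gene name here also passed 2-fold. In the double-positive population 172 of 4068 measured were higher and 25 lower, and in the tdTomato-only population 224 of 3931 were higher and 38 lower.

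Paneth cell genes were far above the EGFP-only level in the double-positive population. A mixture of the other 2 populations would need a share of at most 1, equal for all genes, but the Paneth cell genes needed a median share of 1.372 (quartiles 1.25 to 1.47, 6 unsaturated genes in the authors' deposited ratios) against 0.739 for 20 goblet cell genes (0.413 to 0.942). On these arrays this argues against a mixture. The quartiles are spreads over genes, and 1 array per population gives no error between sorts. A dye effect would not follow a gene's function, yet the list median exceeded the upper bound of the central 95% of random lists by 3.726, although the third comparison, where a shared dye effect cancels, does not decide with its median of −0.32. EGFP-positive cells sorted while attached to Paneth cells stay open. The 32 stem cell genes other than Lgr5 had a median of −0.3034 with quartiles of −0.49 and 0.005. Their spread (SD 0.74) was larger than that of all genes (0.57), where dilution asks for about 1 amount in genes that the attached cell lacks. The list also holds genes such as Ephb3, which Paneth cells also express, and the offset shrinks dim genes most, so this spread cannot decide. Lgr5 cells of Paneth-like expression that descend from Atoh1-expressing cells, which the design names, remain an untested explanation beside attached cells.

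Lymphocyte genes were higher in the double-positive population than in both others. Lymphocytes in the gate stay open: 82.35% of the measured list, 14 of 17 genes, was at least 2-fold higher, which restates the pattern and does not test its source, with Gzma reaching a normalized log2 level of 12.2 against 8.42 in the EGFP-only population. None of the 22 list genes on the array is held by another list, 17 were above background in the EGFP-only population too, and the labels name a gate on EGFP and tdTomato alone. White cells of all kinds, which would raise over 50% of the B, plasma, myeloid and mast cell genes, stay open. Of those measured, 16.67% (3 of 18) were at least 2-fold higher. In the deposited ratios 8 of 20 were, with an exact binomial interval of 19.1% to 63.9%, which includes 50%. Another 5 were above background in the double-positive population alone. Over all genes 1383 were, against 121 in the EGFP-only population alone, so these 5 do not bear on the question. A dye effect common to both arrays would cancel between the Cy3 channels, where the list median was −0.8902, and no biological explanation was tested.

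In all, 26 genes were at least 2-fold higher in the double-positive population than in both others, led by Acsl6, Lim2 and Pax9. A spot artefact alone on 1 array would leave them at the EGFP-only level on the other, but their median there was 1.18 (quartiles 0.70 to 1.79), which argues against it for the set. It stays open for Acsl6, at −0.02 in the tdTomato-only population. An artefact that added to a real elevation would leave such values as well, so this test cannot decide on it. For lymphocytes in the gate, 23.08% of the genes (6 of 26) are in the lymphocyte list, which by the limit of 25% set beforehand would count against them, but the list holds only part of a lymphocyte's genes and 1 more gene would have passed the limit. The excess over the EGFP-only level in the tdTomato-only population was taken as a share of that in the double-positive one. Its median was 0.290 (0.259 to 0.310) for these 6 and 0.143 (0.106 to 0.271) for the other 20. Those 20 hold Fcer1g, of the myeloid or mast cell list (1.88 in the double-positive and 0.76 in the tdTomato-only population), so they are not free of white cell genes. The quartiles overlap, so lymphocytes cannot be told apart from other sources. This reading followed 2 changes made after values were seen, since a first form of the excess test, on all measured lymphocyte genes at least 2-fold higher, gave quartiles apart from those of the 20 and counted against lymphocytes, but set genes picked for this pattern against genes that were not.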

How the results depend on the processing

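The blank-subtracted setting was added after the data were seen, and all others were chosen beforehand. Numbers are genes higher, then lower, for double positive and tdTomato only against EGFP only, then tdTomato only against double positive. Median centring alone gave 364 and 740, 407 and 850, and, close to before, 87 and 27. The authors' deposited ratios gave 1516 and 435, 1595 and 864, and 216 and 215. Subtraction of the blank mean with loess gave 1173 and 402, 1225 and 593, and 206 and 163. Quantile normalization moved the lower genes to 107 and 252. The stricter filter gave 392 higher in the first comparison and 15 lower in the third. At 1.5-fold there were 1262 and 485, 1417 and 758, and 302 and 204, and at 4-fold 182 and 1, 214 and 1, and 16 and 7. Genes shared by both tdTomato populations numbered 284 higher and 551 lower with median centring and 1110 and 289 in the deposited ratios, and 72 lower after quantile normalization. No background correction, no filter, the brightest probe and the direct comparison stayed within 1.5 times. The rule of size and the stricter filter act through their own construction, and otherwise the cause was not tested.

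Beside the sign changes given next, which are those of medians outside the central 95% of random lists, of 69 list medians 44 moved by at least 0.083, the SD between the 2 EGFP-only measurements, with median centring, 34 after quantile normalization, 11 without the filter, 51 in the deposited ratios and 36 with the blank mean subtracted. The median of the Wnt list in the tdTomato-only population turned from −0.15 to 0.0228 without the filter, and that of the dissociation and immediate early list in the double-positive population from 0.80 to −0.1398 with median centring. Of 122 named values at least 2-fold from the reference, none changed sign under the 5 settings run on them, and 9 fell under 2-fold with median centring. Among those under 2-fold, median centring changed the sign of Btg1 and Ndufa1 in the tdTomato-only population and of Eef2, Hopx, Lgr5 and Ndufa1 in the double-positive one, and the deposited ratios that of Eef2 there. Signal near background limits dim genes: under the offset their ratios are pulled towards 0. With the blank mean subtracted and loess kept, 189 of 225 named values lay farther from 0. In the deposited ratios, which also leave out loess, 141 did. No leave-one-out or paired analysis was possible because each sorted population was set against the EGFP-only one on 1 array.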

Other observations

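Ribosomal protein genes had median log2 ratios of −0.45 in the double-positive and −0.59 in the tdTomato-only population over 57 genes, and −0.23 between the 2, each below all 10000 random lists and negative under every setting run. The first 2 were −0.94 and −1.19 in the deposited ratios and −1.23 and −1.41 with median centring. The third shrank to −0.11 with median centring and to −0.05 after quantile normalization. That last value is smaller than the SD of 0.083 between the 2 EGFP-only measurements. Rps3 was at −1.38 and −1.62 and Rps9 at −0.96 and −1.34. Respiratory chain genes had medians of −0.13, −0.09 and 0.05, with none past 2-fold and Ndufa1 at 0.77 and 0.66, both just below 0 with median centring. Against the EGFP-only population these medians were −0.56 and −0.56 in the deposited ratios and −0.96 and −0.85 with median centring. Epithelial identity genes had medians of −0.09, −0.04 and −0.01, with Vil1, which encodes villin, at 0.86 and 1.10 and Epcam at −0.55 and −0.64, and with Lgals4 at 1.11 between the 2. With median centring the first 2 medians were −0.80 and −0.55, and the third was above 0 under 3 of the 5 other settings. Housekeeping genes had medians of 0.01, −0.33 and −0.17, the first below 0 under 3 settings and with a mean of −0.17 (−0.78 and −0.85 for the first 2 with median centring), and Ppia was the only member past 2-fold.

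Between the 2 tdTomato populations 15 of 21 Notch genes and 17 of 25 Wnt genes lay below 0, with medians negative under every setting run, but no Notch gene was past 2-fold, and Lgr5 (−1.14) and Ephb3 (1.04), past it in the Wnt list, are also in the stem cell list. The Notch list had medians of 0.07, 0.03 and −0.09, the first 2 below 0 with median centring, and its members past 2-fold were Dtx1 (1.03) in the double-positive and the receptor gene Notch1 (−1.02) in the tdTomato-only population. The Wnt list had medians of 0.05, −0.15 and −0.13, the first below 0 under 2 settings and the second above 0 under 1. Its members past 2-fold included Ephb3, the feedback inhibitor gene Nkd1 (1.67 and 1.34), Wnt3 (1.35, with 0.87 in the tdTomato-only population), which Paneth cells also express, and Myc (−1.08 in the tdTomato-only population). The reserve or +4 cell list had medians of 0.10, −0.17 and −0.17, the first below 0 under 3 settings, with Hopx at 0.60 in the double-positive and Lrig1 at −0.74 in the tdTomato-only population and Msi1 past 2-fold in both. Hopx turned to −0.31 with median centring. Cell cycle inhibitor genes had medians of 0.29, 0.20 and 0.04, of no stable sign, with Btg2 and Cdkn1a past 2-fold in both tdTomato populations. The MHC class II list, with 3 measured genes, had medians of −0.21, −0.63 and −0.42, the first 2 at −0.66 and −1.11 in the deposited ratios and −1.07 and −1.39 with median centring. Its means were 1.11 and 0.67 in the first 2 comparisons, because Ciita, the transactivator of these genes, was at 3.87 and 3.32 while H2-Aa (−0.33 and −0.69) and Cd74 (−0.21 and −0.63) lay below 0.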
